A study of Mus musculus with 6 samples.

How the data were processed

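The assay was acRIP-seq, in which an antibody against N4-acetylcytidine (ac4C), an acetylated form of cytidine in RNA, pulls down RNA fragments that are then sequenced. The cells were 32D, a mouse bone marrow cell line that grows in interleukin 3 (IL-3), given at 10 ng/mL per the labels' protocols. Per the labels, poly(A) RNA was taken from total RNA, and there were 6 libraries in 3 groups, with 2 libraries each for the ac4C antibody, for control IgG and for input RNA. Nothing in the labels says whether the libraries of a group came from separate cultures. The sources used here name cutadapt, Bowtie2, MACS2 and the mouse build GRCm39, per the submitters' processing notes, with no versions or parameters. Which library served as the control for peak calling is not given in the sources used here.

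The values came from 1 list of peak summits made by the authors. Each of its 1876 entries holds an Ensembl transcript and gene, the summit position in nt on that transcript, a region (5' untranslated, coding or 3' untranslated), and 3 scores. Per the file headers these scores are the fold enrichment, a ratio, and the −log10 of the p-value and of the q-value of the authors' peak caller. The names of the entries read as 1 call on the merged ac4C libraries, so no value belonged to a single library. For this reason there is no replicate error, the depth of each library is unknown, and the planned tests of the ac4C libraries against input and against IgG were not run.

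The values themselves were examined to learn what the fold is relative to. All 1876 folds were whole multiples of 0.475, within 0.01 of a multiple. MACS2 computes a fold as the pileup plus 1 over the background plus 1, and that step gives 1 background of 1.11 fragments for every entry. The −log10 p-values of the authors' deposited table followed from the Poisson tail of the pileup over that background, with a largest relative deviation of 0.00044%. The fold is therefore the height of the ac4C pull-down at the summit over a constant, and it has no term for how abundant the transcript is. A tall summit can come from strong pull-down or from a transcript with many copies. The peak numbers in the list ran to 33651, and 1824 numbers, or 5.42% of that, were listed. Of the peaks with several summits, 445 were listed, their letters imply at least 968 summits, and 497 of these were present. Most numbered peaks are thus not among those analysed here, and the filter is not given in the sources used here. A gene without a listed summit can be unexpressed, unacetylated or left out by that filter. A listed summit does not by itself show ac4C, since the fold and p-value hold no input or IgG term.

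Gene symbols were matched to a RefSeq gene table of assembly GRCm38.p6, used for names, gene types and to find which genes neighbour each other; its coordinates are not given here. Of 1485 gene symbols, 1475 matched, by current symbol or by an unambiguous older one, and the other 10 kept their name from the list. The genes and regions assigned by the authors were used as they stand. The plan had been to assign both from an annotation of the same build, and no genome or transcript sequence was used here. The positions given below are on transcripts for this reason.

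Before the data were examined, 21 gene lists were fixed. The 12 machinery lists were cytosolic ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, ribosome biogenesis, spliceosome and hnRNP, proteasome, oxidative phosphorylation, glycolysis, chaperones, cell cycle and DNA replication, chromatin regulators, and RNA modification enzymes. The 4 hematopoietic lists were stem and progenitor regulators, myeloid identity and granule genes, IL-3 and JAK-STAT signalling, and apoptosis and p53. The 5 lists of other cell types were B cell, T and NK cell, erythroid, megakaryocyte and non-hematopoietic markers. Of 904 list entries, 2 were missing from the gene table and were left out.

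The share of summits in each region was given with an exact Clopper-Pearson 95% interval. Each list's share of genes with a summit was compared by two-sided Fisher's exact test with the machinery genes outside the list, because most machinery genes are used in dividing cells. Fold enrichment by region was compared between summits, and by list between genes at their highest fold, for lists with at least 5 genes with a summit. Both used a two-sided permutation test of the difference in median log2 fold with 100000 permutations, for which 1e-05 is the smallest p they can give. The p-values were adjusted by Benjamini-Hochberg over the 21 lists, the 15 lists with enough genes or the 3 regions, with a threshold of 0.05. These tests run over genes or summits within 1 pooled list. They and the intervals cover counting error only, not the spread between cultures. Reads of transcripts that share sequence can be split among isoforms, paralogs or pseudogenes, so several summits of 1 gene on different transcripts may be 1 site.

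The genes named in the text follow a rule fixed before the data were examined. It takes the 15 genes with the highest fold, the 5 genes with the most summits, the 3 members with the highest fold of each list, non-coding genes among the 20 highest folds, and 17 genes tied to ac4C, hematopoiesis or IL-3 signalling. Other genes named below were chosen after their values were seen. Values of some single genes that the rule takes are not reported here.

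The tests were first run on simulated data. Over 895 genes, a list share lowered to 0.1 times was recovered in 100% of runs for lists the size of the cytosolic ribosomal proteins and of oxidative phosphorylation, and in 70% for the proteasome. A doubled share was recovered in 95%, 83% and 43% of runs. Over 1485 genes, a fold multiplied by 2 was recovered at an unadjusted p under 0.05 in 92% of runs for oxidative phosphorylation, 78% for ribosome biogenesis and 56% for glycolysis. In those runs, 50 per list, the same lists with folds shuffled among genes and not multiplied were called in 2%, 4% and 4%. In the runs with a fold multiplied by 3, the lists left unmultiplied were called in 10%, 6% and 6%. A permutation test on shuffled folds calls near its threshold of 0.05 by construction. These rates therefore do not check the test on the real list. In the runs over list shares, 0.25% to 1.45% of unchanged lists were called after adjustment. Of the alternatives tried, the stricter part of the list, with folds at or above the median, was planned. So were a background of all other protein-coding genes, the mean fold of a gene and, for shares by region, the strongest summit per gene. Added after seeing the data were only coding-sequence summits and a background without ribosomal protein genes. Fold by region at the strongest summit per gene was also added then. The software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.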

Results

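RNA from 32D cells, an IL-3-dependent mouse myeloid line, was profiled for ac4C by antibody pull-down. The question was where ac4C, the mark written by the acetyltransferase Nat10, lies on mRNA in these hematopoietic cells. The measurements comprised 2 ac4C libraries, 2 IgG libraries and 2 input libraries, and the values analysed were 1 list of summits called on the merged ac4C libraries. The list held 1876 summits on 1714 transcripts of 1485 genes. No replicate error can be given for any value below, and the depth per library is unknown.

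The tallest summit lay on mt-Nd4 (ENSMUSG00000064363), a complex I subunit encoded in mitochondrial DNA, at nt 1090 of its coding sequence, with a fold enrichment of 260.6; all folds are those of the authors' peak caller. Pkm, which encodes the glycolytic enzyme pyruvate kinase, followed with 198.4 at nt 2287 of ENSMUST00000034834, in the 3' untranslated region. The gene of the postsynaptic scaffold protein Shank1 had a fold of 160.9 in the 3' untranslated region, and that of the interferon-induced membrane protein Ifitm1 had 147.1 in coding sequence. Rpl12, a ribosomal protein gene, reached 131.0 in a 5' untranslated region, and Pf4, the gene of a platelet chemokine, 125.3 in its 3' untranslated region.

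The other genes among the 15 highest folds had varied functions. Fcgr2b, an inhibitory Fc receptor gene, and Fth1, the ferritin heavy chain gene, both had a fold of 111.1. Fold enrichment was 106.8 on Inpp4a, 96.8 on the odorant receptor gene Olfr1423, 95.9 on the tubulin cofactor gene Tbca, and 93.5 on Nudc. The splicing genes Hnrnpa1 and Sf3b5 had folds of 90.7 and 85.9, and Slc3a2, which encodes an amino acid transporter chain, had 84.0. Of the 20 genes with the highest folds, 19 were protein-coding in the gene table and 1, mt-Nd4, had no match there. Across all summits the median fold was 11.4, with quartiles of 7.12 and 19.9 and a lowest value of 2.85. The highest q-value in the authors' deposited table was 0.0108.

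Most genes had a single listed summit. The list gave 1 summit for 1186 genes, 2 for 229 and 3 or more for 70. These counts depend on the unknown filter, which left 497 of at least 968 summits in the listed peaks with several. A gene can therefore have had more summits than are listed. Cd47, whose protein is a "do not eat me" signal on blood cells, had the most, with 6, spread over coding sequence and 3' untranslated region with folds from 13.8 to 22.8. The chromatin remodeller gene Chd4 had 5 coding summits with folds from 10.4 to 31.8. The actin-severing protein gene Gsn had 5 coding summits with folds from 6.17 to 15.7, and the endosomal GTPase gene Rab5c had 5 summits with folds from 13.3 to 32.3. Ccdc88b had 4 coding summits with folds from 7.12 to 14.7. The summits of these genes lay on several isoforms, so the number of separate sites is uncertain. Over the list, 195 genes had summits on more than 1 transcript.

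The next question was where along the mRNA the summits fell. Coding sequence held 900 of 1876 summits, or 48.0% (95% interval 45.7% to 50.3%), and the 3' untranslated region held 843, or 44.9% (42.7% to 47.2%). The 5' untranslated region held 133 summits, or 7.09% (5.97% to 8.35%). With only the strongest summit of each gene, the order of the first 2 turned, with 45.9% in coding sequence and 46.7% in the 3' untranslated region. Median summit positions were nt 130 in the 5' untranslated region, nt 730.5 in coding sequence and nt 2236 in the 3' untranslated region. Within 100 nt of the transcript start lay 42 summits in the 5' untranslated region and 32 in coding sequence.

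Most genes carried listed summits in 1 region, which holds by construction for the 1186 genes with a single listed summit. There were 646 genes with coding summits alone, 620 with 3' untranslated summits alone and 90 with 5' untranslated summits alone. Coding sequence and 3' untranslated region both held summits in 94 genes, and 8 genes had summits in all 3 regions. Aars, an alanyl-tRNA synthetase gene, had summits of fold 42.7 in the 3' and 12.3 in the 5' untranslated region. Mki67, the proliferation marker gene, had a 3' untranslated summit of 34.7 and coding summits of 18.0 and 3.80. The share of bases that each region takes up in expressed transcripts was not measured, so these shares are not enrichments over chance.

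Fold enrichment differed modestly between regions. Summits in coding sequence had a median fold of 10.4 (quartiles 6.65 and 19.0; 900 summits) against 12.3 for all other summits, a ratio of 0.846 (permutation test, adjusted p = 0.0121). Medians were 13.8 in the 5' untranslated region (133 summits; ratio 1.21, permutation test, adjusted p = 0.0893) and 12.3 in the 3' untranslated region (843 summits; ratio 1.13, permutation test, adjusted p = 0.096), and neither passed the threshold. In the stricter part of the list, with folds at or above the median, the ratio for coding summits turned to 1.02 (permutation test, adjusted p = 0.748) and that for 3' untranslated summits to 0.976; selecting on the fold itself draws the medians together. Summits of 1 gene may be 1 site, so the strongest summit per gene was also compared, a test chosen after seeing the data. The coding ratio was then 0.857 (permutation test, adjusted p = 0.0381) and the 5' untranslated ratio 1.27 (permutation test, adjusted p = 0.0419). Both passed the threshold, and the 3' untranslated ratio of 1.08 did not (permutation test, adjusted p = 0.254).

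**Figure D1:**
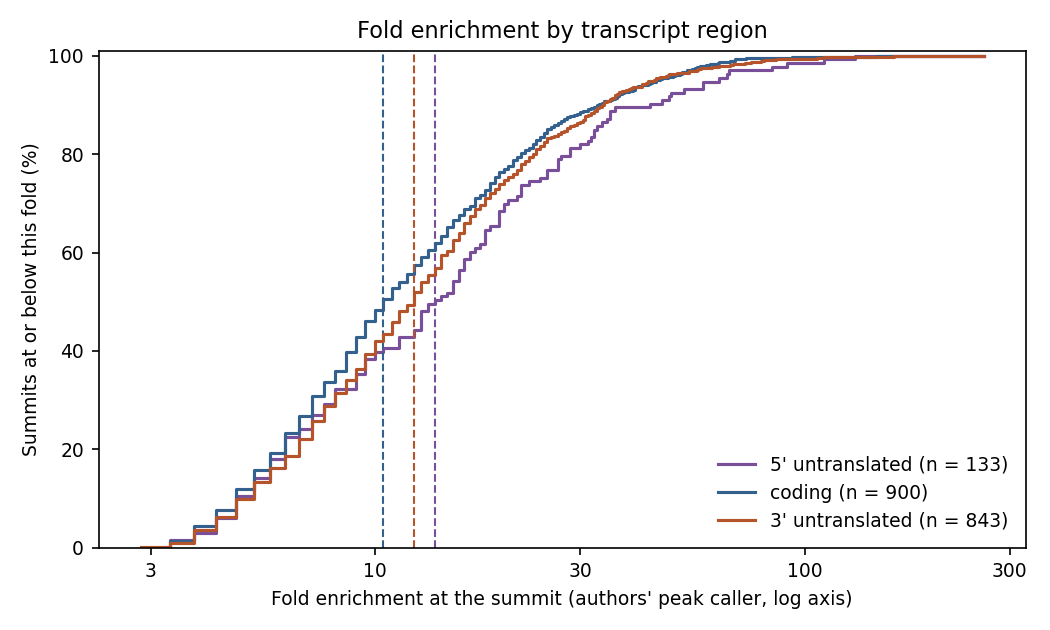
Fold enrichment at each summit (x axis, log scale, no unit) against the percentage of the region's summits at or below it (y axis), for 133 summits in 5' untranslated, 900 in coding and 843 in 3' untranslated sequence; dashed lines are medians. The curves lie close together, with medians of 13.8, 10.4 and 12.3.

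The gene lists asked which functions the genes with a listed summit served. Cytosolic ribosomal protein genes were almost absent, with 2 of 79 genes having a summit, or 2.53% (95% interval 0.308% to 8.85%). Among the other machinery genes, 154 of 535 had one, or 28.8% (odds ratio 0.0643, Fisher's exact test, adjusted p = 2.06e-07). The 2 genes were Rpl12, with a fold of 131.0, and Rpl29, with 8.54. This was the only list of 21 to pass the threshold, and it lost the call against all other protein-coding genes, of which 6.72% had a summit (odds ratio 0.36, Fisher's exact test, adjusted p = 0.245, the highest over its alternatives, which ran from 2.06e-07).

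In other lists of the protein synthesis and RNA machinery, the share of genes with a summit ranged from 10.9% to 42.1%. Splicing and hnRNP genes had 25 of 62, or 40.3% (28.1% to 53.6%; Fisher's exact test, adjusted p = 0.0575), led by Hnrnpa1 at 90.7, Snrpd2 at 73.1 and Sfpq at 37.0. Aminoacyl-tRNA synthetase genes had 8 of 19, or 42.1%, (Fisher's exact test, adjusted p = 0.251), with Aars at 42.7, Kars at 27.1 and Sars at 14.7. Translation factor genes had 16 of 44, or 36.4% (Fisher's exact test, adjusted p = 0.251), with folds of 67.9 on Eif4b, 57.9 on Eif3d and 36.1 on Eif3b. Ribosome biogenesis genes had 12 of 59, or 20.3% (Fisher's exact test, adjusted p = 0.504), with folds of 25.2 on Pno1, 18.5 on Rrp1 and 15.2 on Tsr1. RNA modification enzymes had 5 of 46, or 10.9% (3.62% to 23.6%; Fisher's exact test, adjusted p = 0.0873), and the highest were Rbm15b at 14.7, Nsun2 at 13.3 and Wtap at 13.3.

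Of all machinery genes, 156 of 614, or 25.4%, had a summit, and the metabolic and housekeeping lists ranged from 19.1% to 37.5%. Oxidative phosphorylation had 23 of 70 genes, or 32.9%, and glycolysis 7 of 19, or 36.8%, with Slc16a1, a lactate transporter gene, at 41.8 and Pfkl at 22.8 after Pkm. The proteasome had 12 of 32, or 37.5%, with Psmb4 at 68.8, Psmb7 at 54.6 and Psmc2 at 49.4. Chaperones had 11 of 35, or 31.4%, led by P4hb at 82.1 and by Cct6a and Hsp90ab1, both at 63.1. Cell cycle genes had 22 of 85, or 25.9%, with Cdc20, Mki67 and Top2a each at 34.7, and chromatin regulators 13 of 68, or 19.1%, with Hdac3 at 35.6, Chd4 at 31.8 and Hdac1 at 21.8. Adjusted p-values of these 6 lists ran from 0.276 to 0.894 (Fisher's exact test).

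Among hematopoietic genes, IL-3 and JAK-STAT signalling had summits on 14 of 52 genes, or 26.9%. Its highest were the kinase genes Akt1 at 39.4 and Pim1 at 25.2, and Cish, a feedback inhibitor of cytokine signalling, at 16.6. Stem and progenitor regulators had 9 of 50, or 18.0%, with the transcription factor genes Myb at 51.7, Mycn at 23.3 and Myc at 15.7, all in the 3' untranslated region. Myeloid genes had 6 of 45, or 13.3%, led by Spi1, which encodes the myeloid transcription factor PU.1, at 53.6, the Fc receptor chain gene Fcer1g at 44.6 and Gata1 at 31.8. Apoptosis and p53 genes had 13 of 47, or 27.7%, with Cycs, the cytochrome c gene, at 63.1, the cyclin gene Ccng1 at 40.8 and Birc3 at 21.8. None of the 4 lists passed the threshold against the machinery genes (Fisher's exact test, adjusted p from 0.223 to 0.894).

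Markers of other cell types rarely appeared. Of 90 such genes, 4 had a summit. Among them were Pf4 at 125.3 (1 of 12 megakaryocyte genes; Fisher's exact test, adjusted p = 0.409), Hba-a1, which has a near-identical copy, at 41.8 (1 of 13 erythroid genes; adjusted p = 0.353) and Mbp, a myelin gene, at 6.65. Non-hematopoietic genes had a summit on 2 of 35 (Fisher's exact test, adjusted p = 0.0575). No gene of the 14 B cell markers (upper limit 23.2%; Fisher's exact test, adjusted p = 0.0932) or the 16 T and NK cell markers (upper limit 20.6%; Fisher's exact test, adjusted p = 0.0851) had one. Against all other protein-coding genes 13 lists passed the threshold, all higher, and none of them held markers of other cell types. In that comparison the odds ratios were 0.843 for non-hematopoietic, 1.16 for erythroid and 1.26 for megakaryocyte markers. The B cell and the T and NK cell markers did not pass there either (Fisher's exact test, adjusted p = 0.652 for each). These markers were thus not shown to be rarer than protein-coding genes at large. With ribosomal protein genes left out of the machinery background 4 lists passed, all lower, among them T and NK cell and non-hematopoietic markers. Expression in these cells was not measured, so a low share can also come from genes that are not expressed.

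**Figure D2:**
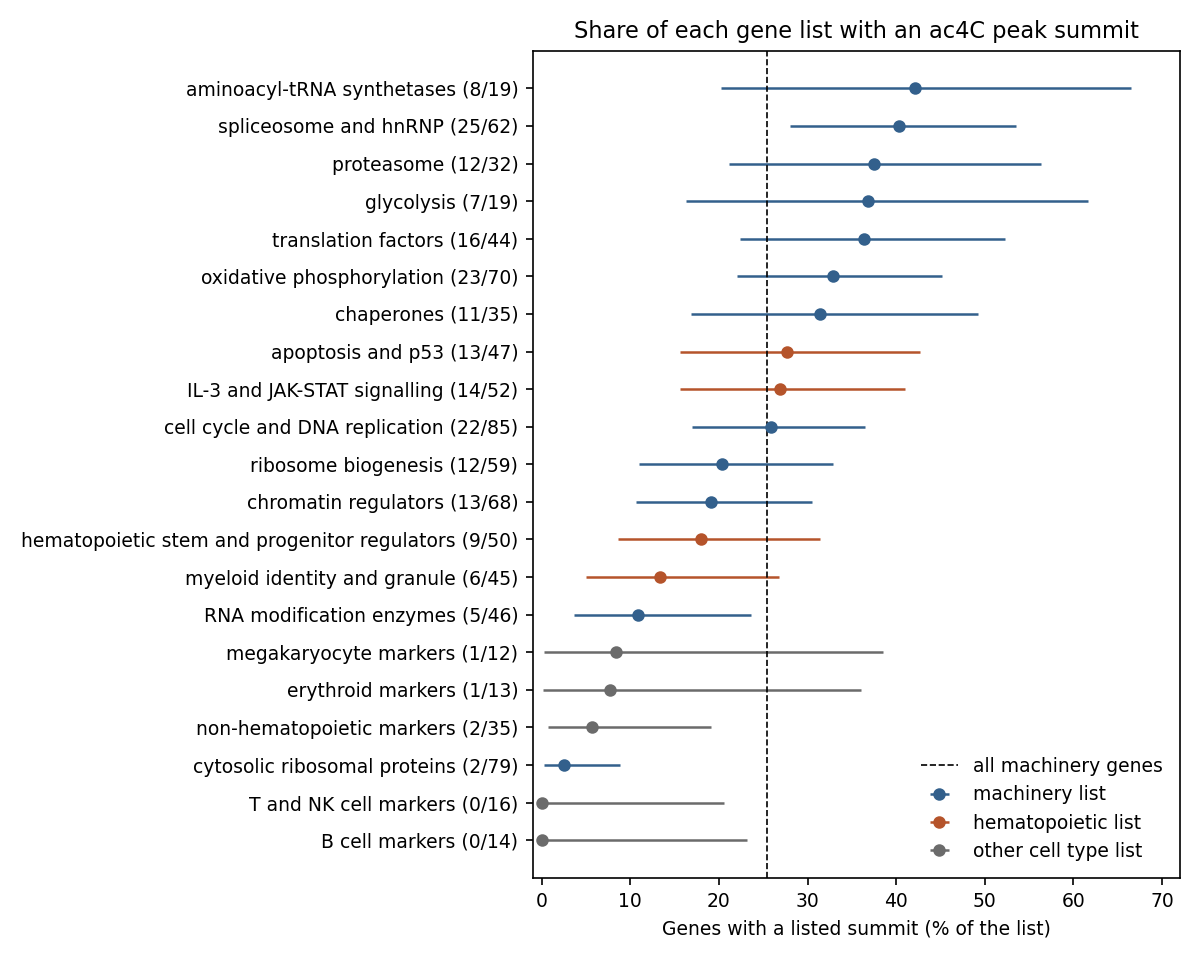
Percentage of each list's genes that have a summit (x axis), with exact 95% intervals as bars and counts of genes beside each name; colours give the kind of list and the dashed line is the share of all machinery genes, 25.4%. The interval of the cytosolic ribosomal proteins, 0.308% to 8.85%, lies below that line, as do those of RNA modification enzymes and of B cell, T and NK cell and non-hematopoietic markers.

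Among genes with a summit, fold enrichment was highest for oxidative phosphorylation. Its 23 genes had a median fold of 35.1 (quartiles 18.5 and 48.7) against 12.3 for the other 1462 genes, a ratio of 2.85 (log2 ratio 1.51; permutation test, p = 1e-05, the smallest the permutations can give, adjusted p = 0.00015). The highest were Atp5a1, an ATP synthase subunit gene, at 63.6 with 3 coding summits, Cycs at 63.1, and Uqcr10, a complex III subunit gene, at 62.7. At the low end were Ndufv1 at 6.65 and Ndufs1 at 4.75, complex I genes chosen after their values were seen.

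No other list of the 15 tested passed the threshold for fold. Medians were 28.7 for the 6 myeloid genes (permutation test, adjusted p = 0.138), 22.3 for the 12 proteasome genes (permutation test, adjusted p = 0.138), 22.3 for the 7 glycolysis genes, 20.9 for chaperones and 19.0 for cell cycle genes. Translation factors had a median of 18.3, splicing and hnRNP genes 16.1 and RNA modification enzymes 13.3. The 6 lists from glycolysis to RNA modification enzymes had adjusted p-values from 0.144 to 0.895 (permutation test). Medians below that of the other genes were 9.97 for stem and progenitor regulators, 9.49 for IL-3 and JAK-STAT signalling, for aminoacyl-tRNA synthetases and for ribosome biogenesis, 9.02 for apoptosis and p53, and 8.07 for chromatin regulators (permutation test, adjusted p from 0.25 to 0.587). Because the fold has no term for transcript abundance, a list can rank high through abundant mRNAs alone.

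**Figure D3:**
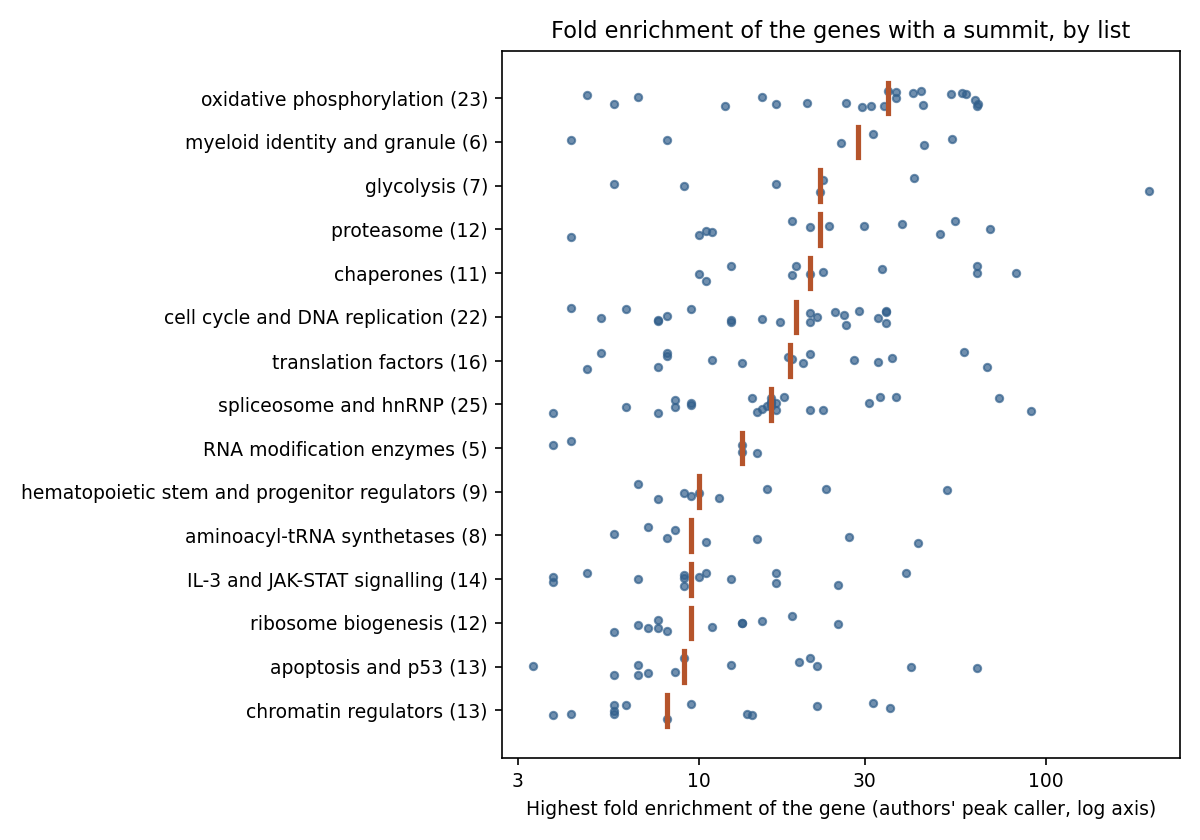
Highest fold enrichment of each gene with a summit (x axis, log scale, no unit), 1 point per gene, by list with the number of genes; bars are medians. The points of oxidative phosphorylation are centred on a median of 35.1, against 12.3 for genes outside the list.

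For 17 genes fixed in advance, 6 had a summit. Spi1 had a fold of 53.6 in the 3' untranslated region, and the cell cycle inhibitor gene Cdkn1a 19.5 in the same region. Myc had summits of 15.7 in the 3' untranslated region and 11.4 in coding sequence. Csf2rb, which encodes the signalling chain of cytokine receptors that include that of IL-3, had a coding summit of 9.02, and the survival gene Bcl2l1 a 3' untranslated summit of 9.02. Stat5b had 3' untranslated summits of 3.80 and 3.32, near the low end of the list. No summit was listed for Nat10 itself or for its adaptor gene Thumpd1, nor for Kit, Runx1, Gata2, Cebpa, Mpo, Jak2, Stat5a, Mcl1 or Trp53. A gene without a listed summit is not shown to lack ac4C, and a listed summit alone does not show that ac4C is present.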

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

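The tests with only coding-sequence summits, with a background without ribosomal protein genes and of fold by region at the strongest summit per gene were chosen after seeing the data. No paired analysis was possible because the summits carry no values per library, so leaving out a replicate and blocking by replicate number gave no value either. Depth is unknown, and the pileup at the summits ran from 5 to 548 with a median of 23. The cause of each change below was not tested unless stated.

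In the stricter part of the list, the number of genes went from 1485 to 811 by construction, the coding share of summits to 44.2% and the 3' untranslated share to 47.5%. The ratio of median folds turned to 1.02 for coding and 0.976 for 3' untranslated summits, in a selection on the fold itself that draws medians together. Odds ratios turned to 0.939 for aminoacyl-tRNA synthetases, 0.534 for IL-3 and JAK-STAT signalling and 0.742 for apoptosis and p53. Fold ratios turned to 0.833 for splicing and hnRNP genes, 1.11 for chromatin regulators and 1.10 for apoptosis and p53. With the mean fold of a gene, RNA modification enzymes turned to 0.759. None of these turned values was past the threshold before, except that for coding summits. With the strongest summit per gene, the 5' untranslated ratio was 1.27 and past the threshold.

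Against all other protein-coding genes, 13 lists passed in place of 1, all higher, and the ribosomal proteins lost their call; this background may include genes that these cells do not express. Odds ratios turned to 3.57 for ribosome biogenesis, 3.31 for chromatin regulators, 1.70 for RNA modification enzymes, 3.07 for stem and progenitor regulators, 2.14 for myeloid genes, 1.16 for erythroid and 1.26 for megakaryocyte markers. Without ribosomal protein genes in the background, 4 lists passed, all lower (ribosomal proteins, RNA modification enzymes, T and NK cell and non-hematopoietic markers), and odds ratios turned to 0.841 for the cell cycle, 0.911 for IL-3 and JAK-STAT signalling and 0.952 for apoptosis and p53. With coding-sequence summits, the ribosomal proteins and non-hematopoietic markers, 2 lists, passed as lower, and the same 3 lists turned to 0.534, 0.754 and 0.708. The high fold of oxidative phosphorylation kept its direction and its call under all 3 alternatives run, with ratios from 1.90 to 3.22. Values of single lists that kept direction and side of the threshold numbered 26 in the stricter part, 29 with coding-sequence summits, 14 with the mean fold, 15 without ribosomal protein genes and 3 against all protein-coding genes.

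Not run, for want of sequence or annotation of the same build, were the tests of start and stop codons, exon length, CXX repeats, C content and wobble C with all their alternatives, the middle of the peak, the longest transcript, overlapping genes, lists matched on exonic length, overlap by at least part of a peak, and peaks per replicate. The gene named in the list, planned as an alternative, became the main setting.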

Other observations

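All tests in this part were chosen after the result was seen, except those of neighbouring genes, of summits near the transcript start and of other machinery genes with against without a named pseudogene, whose predictions were written beforehand. The test of ribosomal protein genes without a named pseudogene was chosen after.

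The position of the strongest summit differed between lists. In oxidative phosphorylation it lay in coding sequence in 19 of 23 genes, or 82.6%, against 45.3% of the other 1462 genes (Fisher's exact test, adjusted p = 0.00667 over 15 lists). Ribosome biogenesis genes had 10 of 12, translation factors 12 of 16 and aminoacyl-tRNA synthetases 7 of 8 (Fisher's exact test, adjusted p = 0.103 for each). At the other end were stem and progenitor regulators with 2 of 9 and IL-3 and JAK-STAT signalling with 4 of 14, which did not pass (Fisher's exact test, adjusted p = 0.41 and 0.528). The part of each transcript that is coding was not measured. These shares are therefore not enrichments over chance, and a preference for coding sequence was not tested.

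Of 6 further gene families, compared with all other protein-coding genes, 3 had summits in a larger share of their genes. Coat (Copa, Copb, Cope, Copg and Copz) and numbered Sec genes had 9 of 37, or 24.3% (Fisher's exact test, adjusted p = 0.0036). They were taken by symbol, so not all need serve vesicle transport. Among those with a summit were Copz1 at a fold of 42.7, Copb2 at 28.0 and Sec13 at 21.4. Sorting nexins had 7 of 30, or 23.3% (Fisher's exact test, adjusted p = 0.00625), with Snx3 at 68.8, and mitochondrial ribosomal proteins 12 of 78, or 15.4% (Fisher's exact test, adjusted p = 0.00837), with Mrpl51 at 32.3. Zinc finger genes of the Zfp series had a smaller share, 12 of 397, or 3.02% (Fisher's exact test, adjusted p = 0.00479). Rab GTPases, with 9 of 69, and solute carriers, with 20 of 375, did not pass (Fisher's exact test, adjusted p = 0.0583 and 0.348). Genes not expressed in these cells are part of this comparison, in which 13 of the 21 fixed lists also passed as higher, and none of the 6 shares exceeded the 25.4% of machinery genes.

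Whether short transcripts account for the scarcity of cytosolic ribosomal protein genes, 2 of 79, cannot be told, because transcript lengths were not used. Other groups that include small proteins were listed more often. The counts were 12 of 78 mitochondrial ribosomal proteins (Fisher's exact test, p = 0.00499) and 23 of 70 oxidative phosphorylation genes (Fisher's exact test, p = 3.71e-07). These groups were not matched on length, and some of their summits lay far along, as on Mrpl10 at nt 1276 and Ndufs1 at nt 1208. The 15.4% of mitochondrial ribosomal proteins was also below the 28.8% of other machinery genes. A filter against abundant mRNAs stays open, because abundance was not measured in these cells. A list of 48 other mRNAs presumed abundant was added after the data were seen. Of these, 10 had a summit, or 20.8%, against 28.6% of the remaining machinery genes (Fisher's exact test, p = 0.314). That share was above the 2.53% of the ribosomal proteins (Fisher's exact test, p = 0.00102). Pkm and Fth1, both on the added list, had tall summits, so presumed abundant mRNAs were not all left out. Whether a filter acted on the most abundant mRNAs cannot be told from a presumed list. Loss of reads to pseudogenes stays open in part: 13 of 45 other machinery genes with a pseudogene named after them had a summit, 28.9% (16.4% to 44.3%), against 28.8% of the 490 without, and 0 of the 15 ribosomal protein genes without one did (upper limit 21.8%; Fisher's exact test against those 490, p = 0.0151), which argues against named pseudogenes as the whole cause, while pseudogenes not named after their gene were not counted. No biological explanation was tested.

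Genes of odorant and vomeronasal receptors, which serve the sensing of odours and pheromones, had 29 summits on 25 genes. The gene table held 1459 such genes, so the share with a summit was below the 6.72% of protein-coding genes outside the ribosomal proteins. Of the 29 summits, 28 lay in 3' untranslated and 1 in 5' untranslated sequence. The strongest summit was in coding sequence in 0 of 25 genes (upper limit 13.7%) and in 46.7% of the other 1460 genes, which describes the pattern and does not test its source. A gene of another kind lay within 5000 nt of the locus in assembly GRCm38.p6 for 2 of 25, or 8% (0.984% to 26.0%), and for 172 of 1437 other receptor genes. For most of these genes, this argues against a neighbour within that distance of the annotated locus. The distance was not measured from the summits, which lay at a median of nt 2996 and up to nt 8141 on their transcripts. A neighbour close to the summits therefore stays open. Repeated sequence in long untranslated regions stays open and was not tested, as was any biological explanation. Olfr1423 at 96.8, Olfr143 at 50.3 and Olfr63 at 42.2 had the highest folds. The median fold of the 29 receptor summits was 11.4, and that of the 1847 other summits was also 11.4. By its median, the fold thus did not set the receptor summits apart from the rest of the list.

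The high fold of oxidative phosphorylation genes is not accounted for by summits in coding sequence, nor by a strongest summit within 1000 nt of the transcript start. Position within those 1000 nt and transcript length were not matched, so a narrower effect of either stays open. Outside oxidative phosphorylation genes, the 877 coding summits had a lower median fold than the other 972, with a ratio of 0.846 (permutation test, p = 0.0104). Among genes with the strongest summit within 1000 nt of the transcript start, the ratio of oxidative phosphorylation to other genes was 2.79 (21 genes against 597; permutation test, p = 1e-05, the smallest the permutations can give). Transcript abundance is a candidate explanation, but it was not measured. Of the mRNAs presumed abundant, 10 had a summit, none of them an oxidative phosphorylation gene. Their median fold was 31.6 against 12.3 for 1452 other genes, a ratio of 2.55 (permutation test, p = 0.00129). Pkm, Fth1, Actg1 at 79.3 and Hsp90ab1 were highest. Because the list was presumed and added after the data were seen, the ratio does not measure an effect of abundance. Stronger acetylation of the oxidative phosphorylation mRNAs was not tested, because that needs the input libraries.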
